A study of Caenorhabditis elegans with 2 samples.

How the data were processed

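Chromatin immunoprecipitation followed by sequencing was done on 2 biological replicates of whole L4 larvae, 48 hours old, of a strain with a daf-19 transgene tagged with EGFP and other epitopes. Chromatin was sonicated to fragments of 200 to 800 bp and precipitated with an anti-GFP antibody, per the labels. A control experiment is named in the labels, and its data were not analysed here. The labels call the replicates biological and do not say how their cultures were grown, so a p-value here measures how sites and genes fall in the peak sets of these 2 samples.

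The deposited files are 8 peak lists on assembly ce11. For each replicate there is a ranked list and a thresholded list made from that replicate's alignments, and for the series there are 2 ranked lists, each with a thresholded list, made from the alignments of both replicates. The aligner, the peak caller, the read filters and the normalization are not given in the sources used here. The signal value of each peak is the authors' own, and its scaling to depth or to a control is not stated. It was therefore used to describe, rank or filter peaks within a list. The signals of the 2 replicates were also set side by side, for description only. The deposited ranked lists also give the −log10 of the irreproducible discovery rate (IDR), which measures whether a peak recurs between replicates or between parts of a sample. Each thresholded list was found to hold exactly the ranked peaks with a value of 2 or more, that is an IDR of 0.01 or less. The ranked lists hold 117986 and 117981 peaks for the series, 112641 for replicate 1 and 110961 for replicate 2. The 16 further columns after the 12th in the series-wide ranked lists carry no names and were not used.

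Most peaks have a fixed width: 968 of the 996 conservative peaks are 380 bp wide. The median conservative signal was 125. All of the 42 conservative peaks with a signal below 40 overlap a stronger conservative peak, so the lowest signals belong to shoulders of strong peaks. No file gives read counts, so depth per replicate is unknown and no interval for a peak's signal was made. Wilson intervals of 95% are given for shares of summits or genes and cover counting error only, since neighbouring peaks are not independent.

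The conservative set was the main one. Summits were compared with the WBcel235 sequence and the Ensembl release 115 annotation, whose chromosome lengths hold every peak. Promoter windows ran from 1000 bp upstream to 200 bp downstream of each annotated transcript start. Shares of summits were tested against 10000 random placements on the same chromosomes. The X-box consensus RTHNYYWTRRNRAC was searched on both strands within 100 bp of each summit and in a window centred 1000 bp away, and compared with the exact McNemar test. Other shares were compared with Fisher's exact test or the exact binomial test, all two-sided, with Benjamini-Hochberg adjustment over 24 gene lists. Lists of protein-coding genes were tested against the other protein-coding genes (19973 in all), and the tRNA, snRNA and snoRNA lists against genes of other biotypes. Of 231 gene symbols listed, 230 were found in the annotation. For the signal of each replicate at a conservative peak, the strongest peak of its own ranked list over the summit was taken.

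Groups, gene lists, tests and most of the alternatives were fixed before the data were examined. The genes named in the text were chosen by rule. For each list these were up to 6 members with the strongest peak and the alphabetically first members without one. To them were added the 15 protein-coding genes outside the lists with the strongest promoter peaks, daf-19, unc-119 and the 5 strongest summits outside promoter windows. Alternatives were the other thresholded set, the stronger part of the conservative set, the 2000 strongest ranked peaks, each replicate alone, other promoter and summit windows, stricter and looser consensus sequences, other backgrounds and other overlap rules. The scripts were tested on simulated data. With 150 of 1000 simulated summits placed at an X-box, 176 summits with one were found, and with 30 ciliary genes given a summit, 31 were found among 19973 protein-coding genes. In 20 random sets no test passed. There the X chromosome share was set against the X share of the genome's length. The main X test, against protein-coding genes, was not run on random sets. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.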

Results

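DAF-19 is the RFX transcription factor of the nematode Caenorhabditis elegans, known for binding a promoter element called the X-box and for driving genes of sensory cilia. Its DNA binding was mapped by chromatin immunoprecipitation and sequencing with an anti-GFP antibody in whole L4 larvae of a transgenic strain carrying a tagged daf-19::EGFP copy. The larvae were 48 hours old and had been synchronised as starved L1 animals. There was 1 group with 2 biological replicates and no second condition, so every comparison set the peaks against the genome, against gene lists or against the other replicate. The files hold peaks and no read counts, so the sequencing depth of each replicate is unknown. Positions are on assembly ce11 (WBcel235).

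Of the 100 strongest peaks, 51 lay within 200 bp of a small RNA gene and 8 in promoter windows of ribosomal protein genes. The peak of highest signal lay 279 bp upstream of rpl-3, a large-subunit ribosomal protein gene (III:3867454-3867706, intergenic). Its pooled signal was 782, and the separate values were 439.6 in replicate 1 and 341 in replicate 2. The next peak lay between the divergent genes F44E5.4 and F44E5.5, members of the HSP70 chaperone family, at II:11759335-11759564 with a signal of 711 (403 in replicate 1 and 318 in replicate 2). The third, at V:8500422-8500654, lay in an intron of pxn-1, 25 bp from the snoRNA gene ZK994.7, with a signal of 629.

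The conservative set for both replicates together held 996 peaks, or 935 after overlapping peaks were merged, covering 362085 bp (0.361%) of the nuclear genome. Replicate 1 alone gave 408 peaks and replicate 2 alone 394. Of the 380 merged replicate 1 peaks, 238 (62.6%; 95% Wilson interval 57.7 to 67.3) overlapped a replicate 2 peak, against 0.271% for randomly placed peaks (permutation p = 0.0002, the smallest that the 10000 placements can give). In the other direction, 238 of 362 merged replicate 2 peaks (65.7%) overlapped. Of the 996 conservative peaks, 251 overlapped thresholded peaks of both replicates, 112 of replicate 1 alone, 102 of replicate 2 alone and 531 of neither. At 931 conservative peaks both replicates had a ranked peak over the summit. There the median ratio of replicate 1 to replicate 2 signal was 1.13, which is not a measure of binding because the scaling is unknown. Across peaks the Spearman rho was 0.543 and the Pearson r of log2 signal 0.763. These peaks are not independent replicates and were selected by the threshold.

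**Figure D1:**
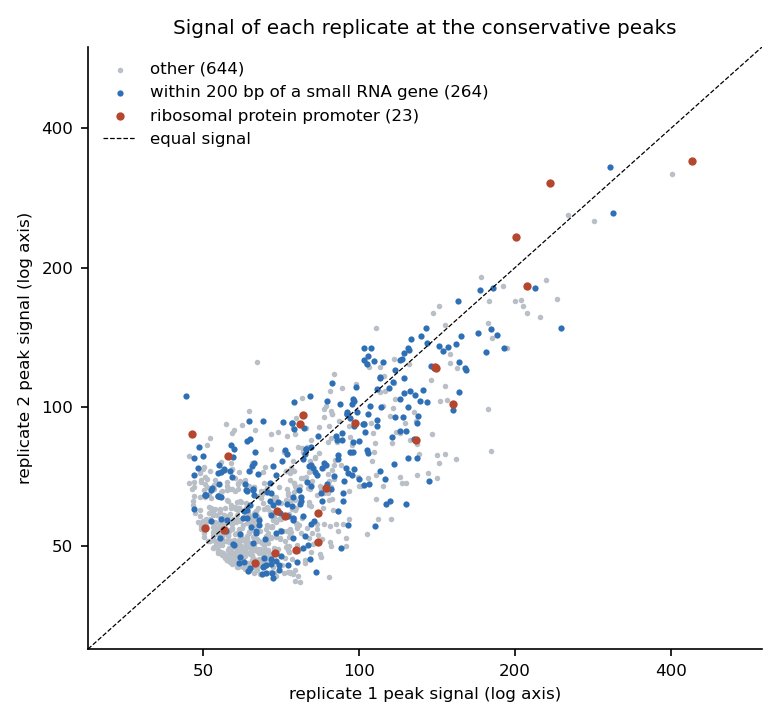
Peak signal of replicate 1 (x axis) and replicate 2 (y axis), both on log axes, at the 931 conservative peaks with a ranked peak in both; colours mark summits near small RNA genes, those in ribosomal protein promoters and all others, and the dashed line marks equal signal. The rpl-3 peak stands at the upper right, at 439.6 and 341.

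The question of where in the genome the tagged factor was found was addressed with the summits. Promoter windows of protein-coding genes, from 1000 bp upstream to 200 bp downstream of a transcript start, held 431 of 996 summits (43.3%; 95% Wilson interval 40.2 to 46.4). Random placement on the same chromosomes gave 25.7% (permutation p = 0.0002, the smallest that 10000 placements can give). The share was 44.4% in replicate 1 alone and 43.1% in replicate 2 alone. By the annotation of protein-coding genes alone, 499 summits lay outside genes, 289 in introns and 141 in coding sequence. Another 38 lay in 3' UTRs, 25 in 5' UTRs and 4 in other exons. Small RNA genes and pseudogenes were not counted as genes here, so some of the 499 summits lay inside them.

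Outside the fixed gene lists, the promoter windows with the strongest peaks after F44E5.4 and F44E5.5 included tasp-1 (III:10759197-10759329, signal 508), which codes for a threonine aspartase. They also included cdc-48.1 (II:10563498-10563656, signal 376), a AAA ATPase gene, rpa-2 (I:4769566-4769676, signal 368), a replication protein A gene, and mog-4 (II:14561801-14561920, signal 363), a splicing helicase gene. The windows of nspc-17 on X (signal 444), mtcu-2 on II (signal 375), Y17G9B.5 on IV (signal 539, shared with rpl-20) and tag-340 on III (signal 293, shared with nhl-2) followed the same rule. For another 6 of the 15 genes named by this rule, the summit lay within 200 bp of an annotated small RNA gene. These were H41C03.3 (signal 422) next to the spliced leader gene sls-2.1, egg-5 (signal 409) next to sls-2.4, and sre-23 (signal 286) and F59C6.18 (signal 277) next to snoRNA genes. C28G1.2 (signal 308) and the potassium channel gene kvs-3 (signal 279) had a tRNA gene there. Of the 5 strongest summits outside every promoter window, those in introns of pxn-1 and frm-7 (V:12303534-12303735, signal 574) lay at snoRNA genes. The other 3 were intergenic: IV:4727959-4728141 (signal 543), X:11094094-11094280 (signal 459) and IV:4725445-4725824 (signal 409). Those on IV lay near the same pseudogene, WBGene00023323, at 71 and 329 bp from it. The latter also lay 181 bp from the noncoding RNA gene WBGene00195021. The peak at X:11094094-11094280 had no ranked replicate 2 peak over its summit.

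Small RNA genes stood near a large part of the summits: 283 of 996 (28.4%; 95% Wilson interval 25.7 to 31.3) lay within 200 bp of a tRNA, snoRNA, snRNA or rRNA gene. Random placement gave 0.551% (permutation p = 0.0002, the smallest possible); this distance was chosen after the peaks had been seen. tRNA genes accounted for 209 summits, 71.4-fold over random placement, snoRNA genes for 54 and snRNA genes for 22. No summit lay near an annotated rRNA gene, where random placement put only 0.0151% of them. The share was higher among strong peaks. It was 122 of the 249 peaks with the highest signal (49.0%) and 40 of the 249 with the lowest (16.1%) (Fisher's exact test, two-sided, p = 3.32e-15). Promoter windows of ribosomal protein genes held 24 summits, 23.1-fold over random placement, and 8 of them were among the 100 strongest peaks.

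**Figure D2:**
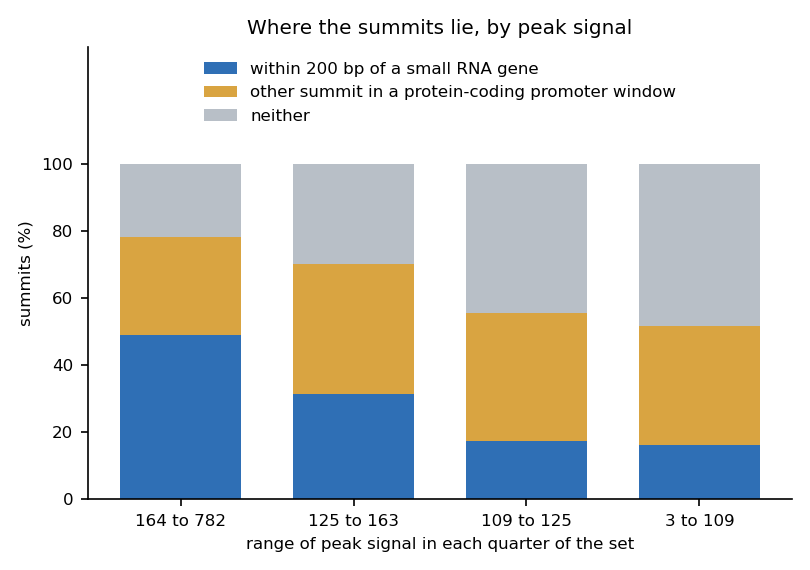
Share of summits (y axis, %) within 200 bp of a small RNA gene, in a protein-coding promoter window without such a gene, or neither, for each 249 of the conservative peaks ordered by peak signal (x axis, range of signal). The share near small RNA genes runs from 49.0% in the strongest 249 to 16.1% in the weakest 249.

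The X-box, the element through which DAF-19 is known to act at ciliary genes, was rare at the summits. Its consensus RTHNYYWTRRNRAC occurred within 100 bp of 7 of 996 summits (0.703%; 95% Wilson interval 0.341 to 1.44) and in 14 flanking windows (1.41%) centred 1000 bp away, a difference that did not pass the test (exact McNemar test, two-sided, p = 0.189). The 7 summits, named after their positions were seen, lay in the promoter windows of C33B4.4, idhg-1 (shared with mlcd-1), F28H6.8, M163.11 and nas-10, in an intron of F52C9.5 and in the 3' UTR of cbd-1, and none is a gene of the ciliary lists. Replicate 1 alone gave 4 of 408 and replicate 2 alone 3 of 394. Against windows at the same distances from random transcript starts, 1.71% of which held the consensus, the share at the summits was lower (permutation p = 0.0198, the smallest that 100 draws can give). These windows were not matched on base composition, and median GC was 42.3% in summit windows against 35.3% in random ones. The consensus with its positions shuffled lay at 1.17% of summits (permutation p = 0.476). Its 20 draws are too few to pass the test. The same direction passed the test in the 10000 strongest ranked peaks, a set added after the data were seen, with 1.39% of summits against 1.78% of flanks (exact McNemar p = 0.031). The difference ran the other way without passing in the 2000 strongest ranked peaks, with 1.35% of summits against 1.1% of flanks (exact McNemar p = 0.56), and with a looser consensus, with 25.5% against 25.2% (exact McNemar p = 0.919).

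Strong peaks held the X-box no more often than weak ones: 1 of the 249 strongest and 4 of the 249 weakest peaks (Fisher's exact test, two-sided, p = 0.372). Of these 4 weak peaks, 3 had a signal below 40, overlapped a stronger peak and lay within 200 bp of a tRNA gene, which leaves 1 without them. In the 2000 strongest ranked peaks the difference passed the test in the same direction, with 2 of the 500 strongest and 12 of the 500 weakest of them (Fisher's exact p = 0.0123).

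Nearly all genomic X-boxes were without a peak. Of the 9157 matches in the nuclear genome, 5 of the 2469 in promoter windows (0.203%) and 2 of the 6688 elsewhere (0.0299%) lay within 100 bp of a summit (Fisher's exact test, two-sided, p = 0.018). This difference rested on 5 promoter matches and was lost in the other thresholded set for both replicates, with 3 of 2469 against 8 of 6688 (Fisher's exact p = 1). Of the promoter summits with an X-box, those of F28H6.8, M163.11 and nas-10 had signals of 23.5, 12.5 and 11.2 and overlapped a stronger peak. In each replicate alone 1 promoter match was occupied, against 4 elsewhere in replicate 1 and 2 elsewhere in replicate 2.

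Genes of the sensory cilium, the known targets of DAF-19, carried hardly any thresholded peaks in their promoter windows. Of 69 ciliary genes, 2 (2.90%; 95% Wilson interval 0.799 to 9.97) had a summit in their promoter window, against 493 of 19904 other protein-coding genes (2.48%). The difference did not pass the test (Fisher's exact test, two-sided, p = 0.689), and the same count of 2 genes was found in each replicate alone. The members with a peak were ift-43, a gene of intraflagellar transport complex A (summit at II:5661599, signal 230.7, with 143 in replicate 1 and 75.9 in replicate 2), and tmem-107, a transition zone gene. The ift-43 summit lay 813 bp upstream of its start, inside an exon of another gene, mdt-26. The tmem-107 summit at I:14759498 had a signal of 305 (169 in replicate 1 and 144 in replicate 2). It also lay in the window of the ribosomal protein gene rps-26, which starts in the opposite direction, and within 200 bp of the snoRNA gene F39B2.14.

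**Figure D3:**
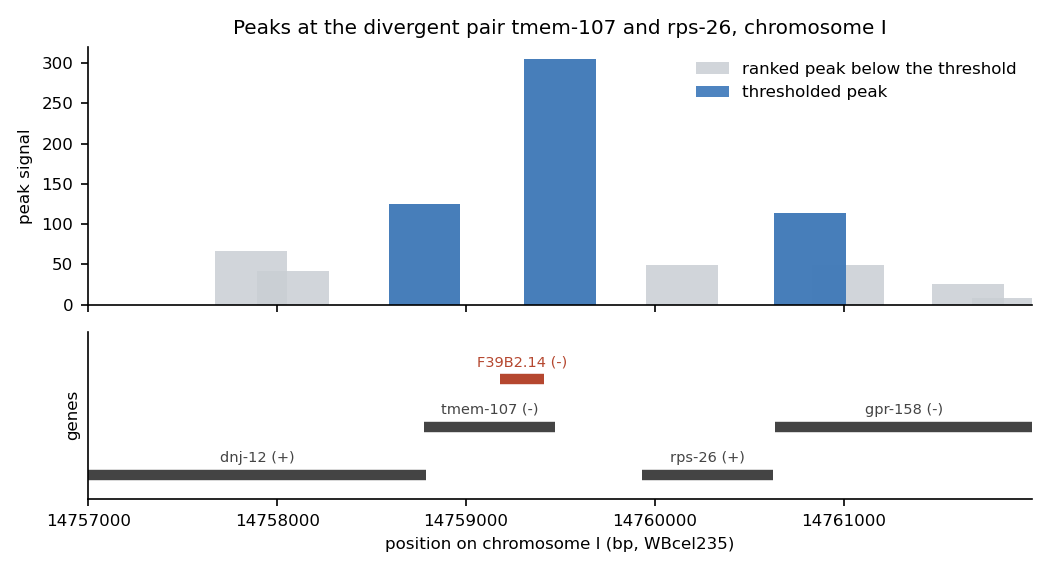
Peak signal (y axis, upper panel) of thresholded and other ranked peaks along chromosome I (x axis, bp), with annotated genes and their strands in the lower panel. The peak of signal 305 lies between the starts of tmem-107 and rps-26.

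No member of the lists for intraflagellar transport complex B (14 genes, among them che-2, che-13 and dyf-1), ciliary motors (7, among them che-3 and kap-1), the BBSome (8, among them arl-6, bbs-1 and bbs-2) or other ciliary genes (17, among them arl-13 and arl-3) had a summit in its window. Complex A had 1 of 6 members (adjusted p = 0.559, Fisher's exact test with Benjamini-Hochberg adjustment over 24 lists) and the transition zone 1 of 17 (adjusted p = 0.97, same exact test). No summit lay in the windows of the 6 male-specific ciliary genes, such as cil-7, or of daf-19 itself (II:10157520-10169346). The gene unc-119 (III:10902641-10908935), used to rescue the transgenic strain, had none either.

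Among the 24 lists fixed in advance, 4 passed the test, and none of these was ciliary or neuronal. Ribosomal protein genes had a summit in 23 of 81 windows (28.4%) against 2.37% of other protein-coding genes (adjusted p = 1.41e-17, Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment). After rpl-3, the strongest were rpl-20 (signal 539), rpl-15 (signal 449), rpl-35 (signal 386), rps-26 (signal 305) and rpl-7A (signal 265), while rla-0, rla-1 and rla-2, which code for acidic stalk proteins, had none. Each replicate alone showed the group, with 15 genes in replicate 1 and 14 in replicate 2.

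tRNA genes had a summit in 243 of 612 windows (39.7%) against 2.18% of genes of other biotypes (adjusted p = 7.06e-219, same exact test). The strongest at a tRNA gene's own position was at X:3035948-3036327, signal 362, beside the tRNA genes WBGene00023110 and WBGene00023111. snoRNA genes, which guide modification of ribosomal and spliceosomal RNA, had one in 67 of 346 windows (19.4%, adjusted p = 2.47e-36, same exact test), among them ZK994.7, C51F7.3 and C51F7.4. snRNA genes had one in 18 of 129 windows (13.95%, adjusted p = 6.74e-08, same exact test). Of these 18, 10 were spliced leader genes of the SL2 type (sls-2), counted after their peaks were seen. The strongest were the spliced leader genes sls-2.1 (signal 422) and sls-2.4 (signal 409), and R07E5.16 (III:10989804, signal 327). In replicates 1 and 2 alone, 142 and 162 tRNA genes, 47 and 48 snoRNA genes and 8 and 11 snRNA genes had a summit. Neighbouring small RNA genes can share 1 summit, so their counts are not independent. Summits can also be shared with protein-coding genes. The rpl-15 summit (IV:654947) was also counted for the snoRNA genes K11H12.12 and K11H12.13. The snoRNA and ribosomal protein lists are thus not fully separate results.

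The other lists did not pass. Histone genes had 5 of 72 windows with a summit (6.94%, adjusted p = 0.159, same exact test), among them his-37 (signal 345) and the divergent pair his-67 and his-68 (signal 164). This list passed in replicate 1 alone, with 4 of 72 genes (adjusted p = 0.037, same exact test), and not in replicate 2 alone, with 2 of 72 (adjusted p = 0.535, same exact test). It also passed in the 2000 strongest ranked peaks, with 9 of 72 genes (12.5%, adjusted p = 0.0215, same exact test). Proteasome genes had 2 of 33, rpn-11 (signal 117) and rpn-8 (signal 105). Synaptic genes had 1 of 18, rab-3 (II:5725376, signal 132), which codes for a synaptic vesicle GTPase. There was no summit in the windows of 16 sensory transduction genes, 17 neuronal transcription factor genes, 13 neuroendocrine genes or 14 innate immunity genes. The same held for 14 body wall muscle, 7 pharynx, 14 intestine, 14 epidermis and cuticle, 14 germline and 12 stress response genes.

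**Figure D4:**
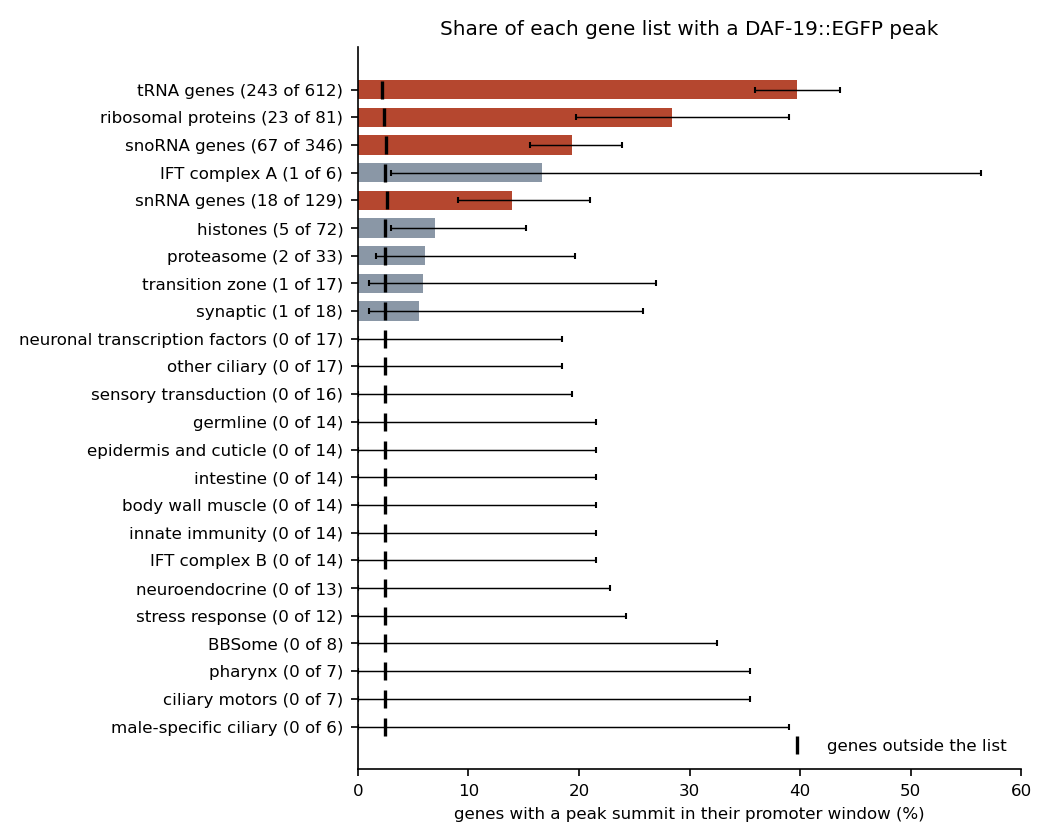
Share of the genes of each fixed list with a summit in their promoter window (x axis, %), with 95% Wilson intervals as lines, red bars for lists with an adjusted p below 0.05, and black ticks for the share among genes outside the list. tRNA genes reach 39.7% and ribosomal protein genes 28.4%.

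The X chromosome carried 216 of 996 peaks (21.7%; 95% Wilson interval 19.2 to 24.4), against 13.7% of protein-coding genes (exact binomial test, two-sided, p = 6.19e-12). Replicate 1 alone had 102 of 408 peaks on X and replicate 2 alone had 26.4% there. tRNA genes are concentrated there, with 276 of 612 on X, and 56.9% of the 209 summits near tRNA genes were on X. Without those 209 summits, a comparison added after the data were seen, 97 of 787 peaks (12.3%) were on X, and the difference from protein-coding genes no longer passed and had the opposite sign (exact binomial p = 0.299). Against the X share of the nuclear genome's length, 17.7%, also a comparison added later, the excess of all 996 peaks was smaller (exact binomial p = 0.00118).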

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

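The larger promoter share of summits and the replicate overlap kept their direction and their side of the threshold under every alternative run, as did the shares of ribosomal protein genes and, with the exception below, of tRNA, snoRNA and snRNA genes. The settings that merged peaks, removed summits near small or tRNA genes, used the 10000 strongest ranked peaks, or changed the background of the biotype lists or of the X share were chosen after seeing the data. The number of gene lists past the threshold was 4, and 4 to 5 under the alternatives that kept every summit class. Without summits near small RNA genes, ribosomal protein and snoRNA genes alone passed as enriched, and tRNA genes passed as depleted. The removal took every summit within 200 bp of such a gene, while promoter windows reach 1000 bp upstream. Histone genes passed in replicate 1 alone and in the 2000 strongest ranked peaks only. Values are differences in percentage points unless stated, and the cause was not tested except where the setting itself removes the summits concerned.

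The X-box difference turned to 0.25 in the 2000 strongest ranked peaks and 0.301 with the loose consensus. It passed at -1.003 with the promoter-matched background and at -0.39 in the 10000 strongest ranked peaks, and the X-box difference by signal passed at -2 in the 2000 strongest. The higher occupied share of promoter X-boxes kept its call with the loose consensus (0.187) and the narrowest promoter window (0.262). It lost its call in the other thresholded set (0.00189), the stronger part of the set (0.0256), the 2000 strongest peaks (0.0655), with the strict consensus (0), with summit windows of 50 bp (0.081) and 200 bp (0.136) and with the widest promoter window (0.0727), and it ran from -0.0193 to 0.0106 with a replicate left out. The ciliary difference, never past the threshold, turned to -0.0935 in the 2000 strongest peaks, -0.194 with the narrowest promoter window and -0.656 without summits near small RNA genes. The X chromosome difference turned to -1.35 without summits near tRNA genes. Without summits near small RNA genes the shares of tRNA and snRNA genes with a peak were 0%, while 5.78% of snoRNA genes kept one. Every summit in the window of a tRNA or snRNA gene thus lay within 200 bp of a small RNA gene. The proteasome share was 0% in the stronger part of the set and 0% to 3.03% with a replicate left out. With a replicate left out the number of peaks was 394 to 408. No paired analysis was possible because there is 1 group. Depth is unknown, so how it limits weak peaks could not be measured.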

Other observations

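The tests on X-boxes at small RNA genes, on snoRNA and tRNA genes with no shared stretch, on ribosomal protein genes and on ranked X peaks were chosen after the result was seen. Spliced leader genes, whose short RNAs are joined to the start of most messenger RNAs in this animal, were singled out after their peaks were seen. Of the 18 SL2-type genes (sls-2), 10 had a summit in their window, against 0 of the 12 SL1-type genes (sls-1), which lie in a repeated cluster on V. Around daf-19 and unc-119, the genes of the transgene, ranked peaks were not more numerous than in most random spans: daf-19 had 26 within 15000 bp, the percentile 30.1 of random spans of the same length, and unc-119 had 20, the percentile 31.3. The highest ranked signal there stood at the percentile 82.5 for daf-19 and 18.5 for unc-119. The 28 conservative peaks narrower than 380 bp were mostly strong, with 23 among the 50 of highest signal.

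Peaks at tRNA, snRNA and snoRNA genes were weighed first, with no biological explanation but X-box binding tested, and base composition is argued against: the share of summits there was 35.1 times that of random windows matched on GC content. X-box binding as the source of the whole group is argued against only in part. The consensus lay at 1.41% of these 283 summits (4, against 3 flanks, upper 95% Wilson limit 3.58%). A looser one lay at 24.7% (70, against 60 flanks, exact McNemar p = 0.378). The bound written for X-box binding also asked for a share at or below that of the flanks, which was not met. The low limit thus argues only against the consensus lying at most of these summits. Reads shared between near-identical copies of the gene itself are argued against at snoRNA genes. There 20.9% of the 297 genes with no 30-base stretch found elsewhere had a summit (Fisher's exact p = 1.14e-36 against protein-coding genes). Only the gene was checked for such stretches, while its summit could lie anywhere in the promoter window. Shared sequence in the rest of the window was not checked. Without summits near small RNA genes, 5.78% of all snoRNA genes still had one in their window. Shared reads cannot be told apart at tRNA genes, where the values point both ways. Of the 140 of unique full sequence, 28.6% had a summit, against 2.48% of protein-coding genes (Fisher's exact p = 3.55e-30). This met the bound set beforehand. Those with an identical copy had a summit more often, in 203 of 472 (Fisher's exact p = 0.00226 against those of unique full sequence). Genes of unique full sequence can also share shorter stretches. Of the 20 tRNA genes that shared none, only 2 had a summit (10%, Fisher's exact p = 0.0873 against protein-coding genes). Of the 592 that shared a stretch, 241 had a summit. A further cut, outside that bound, kept 21 genes of unique full sequence with no other tRNA gene of 90% identity or more. Of these, 2 had a summit (9.52%, Fisher's exact p = 0.095 against protein-coding genes). Among the 15 of them with no other tRNA gene within 1500 bp, 0 had one. These sets are too small to decide. Capture of open or highly transcribed loci whatever factor is tagged may also account for the group and cannot be told apart here. Ribosomal protein genes had a summit in 28.4% of windows and 63 tissue genes in none. The latter lies near the 2.48% of protein-coding genes and says little. Openness and transcription of these genes were not measured, and peaks of untagged animals or other factors were not analysed here.

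The larger X chromosome share of peaks goes with the density of tRNA genes there: without summits near tRNA genes it was 12.3%, below the 13.7% of protein-coding genes. Of the summits near tRNA genes 56.9% were on X, more than the 45.1% of tRNA genes there. The density of tRNA genes may thus not account for all of the excess. An excess already present before thresholding met the bound written for it. The thresholded share on X, 21.7%, did not exceed the ranked share, 21.9% (exact binomial p = 0.878). Only a further comparison, outside that bound, argues against it as the whole source. With peaks near tRNA genes left out of both lists, the share was 21.8% of ranked and 12.3% of thresholded peaks (exact binomial p = 9.09e-12). The excess of the ranked list away from tRNA genes thus did not carry over. No biological explanation was tested.

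The low number of ciliary genes with a peak in their promoter window was weighed last. It is the absence of an expected excess, since their share of 2.90% was not below the 2.48% of other protein-coding genes. A lack of X-boxes in ciliary promoters is argued against: 51 of 69 ciliary genes (73.9%) had the consensus in their window, 5.99 times the share of other protein-coding genes (12.3%; Fisher's exact p = 1.15e-31). Removal of weak ciliary peaks by the IDR threshold cannot be told apart from a lack of signal: the median percentile of ciliary promoters by their highest ranked signal was 56.6, within the 38.3 to 61.7 of random lists of the same size (permutation p = 0.281). Ranked summits lay within 100 bp of 23 of 63 ciliary promoter X-boxes (36.5%) and of 26.5% of other promoter X-boxes, a difference that did not pass (Fisher's exact p = 0.0836). Cilia form in a small part of the cells of a whole larva, and that dilution may also keep such peaks low, but no value here tests it.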
